A study of Drosophila melanogaster with 3 samples.

How the data were processed

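RNA of wounded and unwounded *Drosophila melanogaster* embryos was compared on 3 arrays with 2 colours, named A, B and C. Per the labels, total RNA was extracted with Trizol and cleaned on RNeasy columns, and it was labelled by amino-allyl reverse transcription. On each array unwounded embryos carried Cy3 and wounded embryos carried Cy5, per the labels. No array had the dyes exchanged, so a dye effect of a probe cannot be separated from wounding. The labels do not say whether the arrays came from separate collections of embryos. The p-values therefore measure only the spread between these arrays, which may be technical.

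The deposited table held 12144 rows with 1 value per array. Every value was negative. The median was −1.001 on array A, −1.01 on array B and −0.997 on array C, and the highest value was exactly −0.01 on each array. The deposited values were read as minus 1 times a linear ratio of the 2 colours, normalized by the authors to about 1 on each array, with a floor of 0.01. This scale and centring were inferred from the values. With the sign removed and log2 taken, the skewness was 0.07 on array A, −0.50 on array B and −0.77 on array C, against −2.43, −1.54 and −1.17 for the deposited values. The scanner, background correction, normalization method and reason for the minus sign are not given in the sources used here. The design had allowed for log ratios or linear ratios, and the log2 of the ratio was taken before testing. The direction of the ratio is also unstated. A high ratio was taken as likely higher in wounded embryos, because the series names wounded embryos first and Cy5 over Cy3 is the usual ratio. The sample titles put unwounded embryos first, so the direction stays open, and results are worded as high or low ratio. No spot intensities were used here, so signal over background is unknown and dim probes could not be filtered.

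Probes are cDNA clones named by library prefix. Of the 12144 rows, 160 control spots were left out: 128 carry the names of plant genes and 32 are fly genomic spots. Of the other 11984 probes, 11887 had a value on all 3 arrays and were tested, and 97 were not. Gene symbols came from the platform annotation, which is old, and were updated by Entrez identifier through a table of the Release 6 plus ISO1 MT assembly. Among tested probes 9839 had 1 symbol, 620 had several and 1428 had none. Over all probes with 1 symbol, 9746 matched by Entrez identifier and 171 kept the older name. Probes with several symbols were given no gene name. The mean of a gene's probes gave 8247 genes. No positions are printed, because the build behind the array design is not given in the sources used here.

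Each probe's log2 ratios were fitted with an intercept only in limma 3.58.1 under R 4.3.3, with moderated variances and Benjamini-Hochberg adjustment over the tested probes at a threshold of 0.05. The prior standard deviation was 0.116 with 3.38 prior degrees of freedom. An exact sign-flip test of 3 arrays can reach no p below 0.25, so calls rest on variances pooled over probes. Errors are SD over 3 arrays, and the number of arrays limits the precision. There is 1 group of arrays, so pairing of replicates does not apply.

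Before the data were examined, 17 gene lists and the rule for naming genes were fixed. The rule took the 15 probes with the highest and the 15 with the lowest mean ratio among those past the threshold with 1 symbol and the same sign on 3 arrays. From each list it took up to 4 members past the threshold, or otherwise the 2 members of smallest p. It also took *ple*, *Ddc*, *puc*, *Mmp1*, *Gadd45*, the Hsp70 genes, *Hml* and *Mhc* where measured. *Mmp1*, *Mhc* and Hsp70 genes other than *Hsp70Ab* had no probe with 1 symbol among the tested probes and were not analysed here. Genes named outside the rule either passed when adjusted over their list alone or are marked as chosen after their values were seen. Lists with at least 5 measured genes were tested on gene means with limma's camera at a preset correlation of 0.01, adjusted over the 17 lists. The result of 1 list is not reported here, and it stays in the counts over all lists. Camera with an estimated correlation and fry were alternatives. A check of direction used an exact two-sided sign test over the wound and heat shock lists.

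Alternatives covered centring, scaling, quantile normalization, missing values, robust moderation, array weights, gene means, thresholds and leaving out each array. Treatment of control spots, of values at the floor, of the linear scale, of probes with several symbols and of clone collections was varied only after the data were seen, as was the estimated correlation with an array left out. On simulated data with the 11887 probes and 200 changed probes in each of 20 rounds, the test recovered 79.5% of probes changed by 0.6 on the log2 scale and 95.7% of those changed by 1, and 5.17% of calls were false. For the 8247 gene means, 3.24% of unshifted lists had p under 0.05, and a cuticle list shifted by 0.3 was recovered in 100% of rounds. The simulated errors were independent between probes and between genes. In the real data the estimated correlation within the cuticle list was 0.30, so these rates may not hold there. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.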

Results

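Gene expression after wounding was measured in wild-type *Drosophila* embryos injured with a laser, set against uninjured embryos on the same array. The 3 arrays, A, B and C, each gave a ratio per probe, with 12110, 12068 and 12086 values. Missing values numbered 34 on array A, 76 on array B and 58 on array C. Ratios are given as log2, and a positive value is a high ratio, likely higher in wounded embryos. The basis is that the series names wounded embryos first and that Cy5, the wounded sample's dye, is usually the numerator. If the deposited ratio runs the other way, every high and low below exchanges.

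Most probes lay close to a ratio of 1. With control spots left out, 31 probes on array A, 28 on array B and 11 on array C lay above a log2 ratio of 1, and 12, 37 and 21 lay below −1. Across 11887 probes, which are not independent replicates, arrays A and C were the most alike (Pearson r = 0.48, Spearman rho = 0.47). Arrays A and B followed (r = 0.38, rho = 0.35), and arrays B and C were the least alike (r = 0.25, rho = 0.24). Identical values in a pair of arrays were found for 39 to 45 probes, so no pair was the same array deposited again. Of all tested probes, 41.7% had the same sign on 3 arrays, where chance gives 25%.

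The comparison asked which transcripts differed between wounded and unwounded embryos. Among genes with a high ratio, *Gadd45*, a stress-inducible gene that acts upstream of stress-activated kinases, had a log2 ratio of 0.85 ± 0.24 (SD, n = 3; probe RH70774), a ratio of 1.80 (limma adjusted p = 0.0441). *Pcl*, which encodes a Polycomb-group protein, had a log2 ratio of 0.95 ± 0.11 (SD, n = 3; SD09488; limma adjusted p = 0.0441). Among genes with a low ratio, *Atf3*, a bZIP transcription factor of the stress response, had −0.44 ± 0.08 (SD, n = 3; GH24653; limma adjusted p = 0.0466). *gnu*, needed for the early embryonic nuclear cycles, had −0.72 ± 0.13 (SD, n = 3; LD12084; limma adjusted p = 0.0441). *Dna2*, a nuclease and helicase of DNA replication, had −0.77 ± 0.17 (SD, n = 3; LD18775; limma adjusted p = 0.0441).

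In total 61 probes had a high ratio and 123 a low ratio at an adjusted p of 0.05, which is 1.55% of 11887 probes. All 184 had the same sign on 3 arrays. Those with 1 gene symbol numbered 44 high and 99 low. The median log2 ratio was 0.51 for high and −0.54 for low calls, so most differences were below 2-fold. Apart from *Pcl* and *Gadd45* above, the high end among probes with 1 symbol was led by the anion exchanger gene *Ae2* at 0.99 ± 0.36, the germ plasm gene *tud* at 0.97 ± 0.38, the POU-domain gene *pdm3* at 0.95 ± 0.30 and *CG12818* at 0.92 ± 0.28. *CG42541* (0.73), *Alms1a* (0.71), *CG17572* (0.71), *ko* (0.68), *Sirup* (0.66) and *CG2808* (0.66) came next. *kek3*, which encodes a leucine-rich repeat membrane protein, was at 0.62, the lysyl oxidase gene *Loxl1* at 0.61 and *CG13606* at 0.60. Among the same probes, the low end was led by *CG4836* at −0.84 ± 0.29, *esn* at −0.83 ± 0.29, *CG32106* at −0.80 ± 0.15 and *CG1116* at −0.80 ± 0.04. *CG7906* (−0.79), *CG8508* (−0.71), *CG31693* (−0.69), *CG4891* (−0.69), *CG10725* (−0.68), *CG9377* (−0.67) and *CG9649* (−0.67) were also low. So were *DIP-zeta*, which encodes an immunoglobulin-domain surface protein of neurons, at −0.69, and the F-box gene *Ppa* at −0.67. Clones of 1 cDNA library, GH, made up 51.2% of low calls and 18.2% of tested probes. Those of another, RH, made up 36.1% of high calls and 8.95% of tested probes. GH also held 11 high calls and RH 2 low calls. The probes of *Atf3* and *Cyp6g1* are GH clones. RH70774 of *Gadd45* and the probes of *DptB*, *Listericin* and *Ccp84Aa* are RH clones, so their ratios may share in this skew. Plant control spots had a median of −0.23. Adjusted p over the 184 calls ran only from 0.0441 to 0.0499. Leaving out array A, B or C left 0 calls each time in limma (smallest adjusted p 0.235, 0.0725 and 0.0514), with 1307, 2365 and 1852 probes at an unadjusted p under 0.05, against 2184 with all arrays. Calls were also 0 on the linear ratio and with each clone library centred (2168 and 2202 probes at an unadjusted p under 0.05), 26 high and 65 low when probes with 1 symbol were tested, and 184 high and 257 low with array weights.

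**Figure D1:**
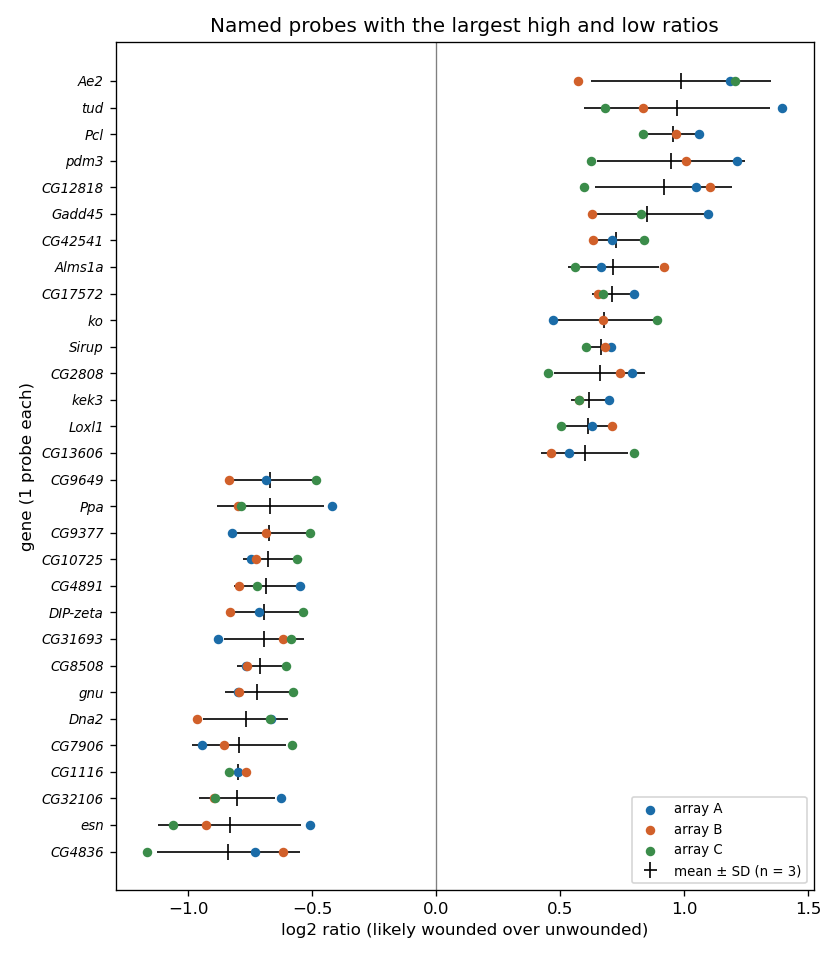
Log2 ratio (likely wounded over unwounded, x axis) of the named probes with the highest and lowest mean ratios past the threshold (y axis, 1 probe each). Points are arrays A, B and C and the bar is the mean ± SD (n = 3); every point lies on the side of 0 of its mean, from 0.99 for *Ae2* to −0.84 for *CG4836*.

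A gene's other probes, from different clones, often did not repeat the difference. *Gadd45* had a second probe at 0.32 ± 0.13 (SD, n = 3; RE18426), which did not pass the test (limma adjusted p = 0.0906), and its gene mean of 0.59 did (limma adjusted p = 0.0411). The probes of *ckd* lay at 0.38 and 0.38, and those of *Dscam2* at 0.42 and 0.32, while a re-amplified spot of the called clone lay at 0.21 for *ckd* and 0.06 for *Dscam2*. The other probe of *Ae2* lay at −0.04, that of *esn* at 0.25 and that of *Fhos* at 0.37, against −0.52 for the *Fhos* probe past the threshold. *Myo28B1* had 0.42 and −0.63. Of the other genes listed above at the high and low ends, the other probe of *CG17572* lay at −0.06 and that of *CG13606* at 0.16. The mean of 2 other probes was 0.13 for *CG42541* and 0.05 for *Ppa*, against −0.67 for the *Ppa* probe past the threshold. Of 25 probes past the threshold whose gene had another clone, 14 shared the sign with it, 12 of 17 with a high and 2 of 8 with a low ratio. The median of the other probes, taken in the direction of the call, was 0.0077 against 0.52 for the called probes. *ckd*, *Dscam2* and *Myo28B1* were chosen after their values were seen.

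**Figure D2:**
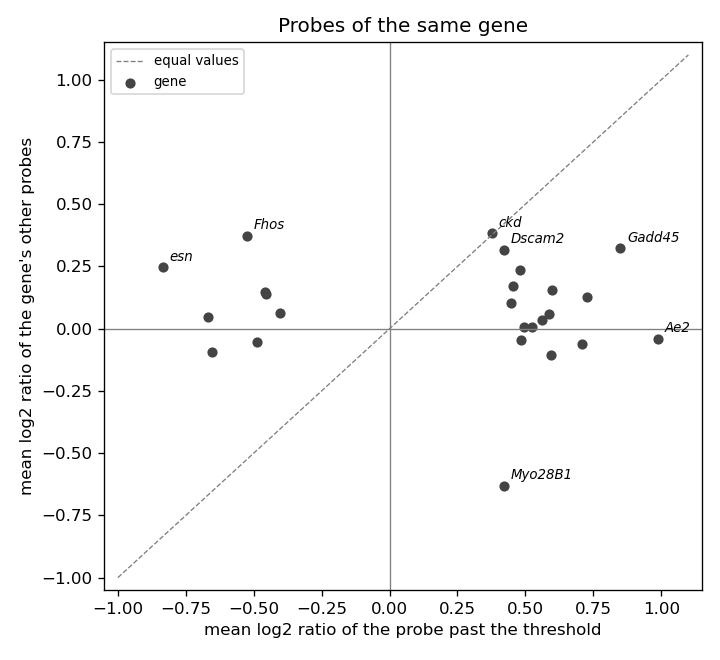
Mean log2 ratio of the probe past the threshold (x axis) against the mean of the same gene's other clones (y axis), 1 point per gene. The dashed line marks equal values; 14 of 25 genes share the sign, and *Gadd45*, *ckd* and *Dscam2* lie above 0 on both axes.

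The direction of the ratio was checked with the wound and heat shock lists. They hold genes known from other work to be induced near wounds or by heat and stress. They also hold pathway components and chaperones that need not be induced, so a count of signs over them is a weak check. *Gadd45* had a high ratio, and *Atf3* and *Fhos*, a formin gene, had a low ratio. *ple*, which encodes tyrosine hydroxylase, had 0.23 and 0.16 on its 2 probes, with array B below 0 on both, and *Ddc*, the dopa decarboxylase gene, had −0.24. The JNK phosphatase gene *puc* had 0.12. *Hsp27* had 0.32, *Hsc70-3* had −0.25, and *Hsp70Ab*, whose near-identical copies make it uncertain, had 0.90 on array A, −0.65 on array B and −0.59 on array C. None of *ple*, *Ddc*, *puc* and these heat shock genes passed the test. Over the 32 measured genes of both lists, 13 had a positive mean and the median was −0.02 (exact two-sided sign test, p = 0.377). The wound list had 9 positive means of 21 (exact p = 0.664) and the heat shock list 4 of 11 (exact p = 0.549). The check did not settle the direction, and without array C the median turned to 0.0055.

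In the epidermal wound list, 1 of 21 measured genes had a high ratio (*Gadd45*) and 2 had a low ratio (*Atf3* and *Fhos*), with a list median of −0.02. Adjusted over the list alone, gene means of *Gadd45* were high and those of *Atf3*, *Ddc* and *shg*, the E-cadherin gene, were low. That adjustment takes no account of the number of lists. Of all 8247 gene means, 1507 had an unadjusted p under 0.05 in limma. A few members that pass over a list alone, here or below, therefore do not set the list apart from other genes. The JNK pathway list had *Gadd45* high and *Atf3* low among 18 genes. Its median was 0.04 and its mean −0.09, and camera placed it upward, so the signs differed. Adjusted over the list alone, the same pair passed. In the list of EGFR, ERK and immediate early genes, *Atf3* was low among 13 genes (median 0.06), over all probes and adjusted over the list alone. The cell death and DNA damage list had *Gadd45* high among 19 genes (median 0.10), and adjusted over the list alone *PCNA* (−0.26) and *PolZ1* (−0.34) were low as well. In the JAK-STAT and Turandot list, 0 of 5 genes passed over all probes, and adjusted over the list alone *chinmo* (0.33) was high and *Stat92E* (−0.70), the pathway's transcription factor, was low.

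In the Toll and Imd list, 0 of 18 genes passed over all probes and the median was 0.04. Adjusted over the list alone, the antimicrobial peptide genes *DptB* (0.33 ± 0.09) and *Drs* (0.31 ± 0.06) were high (SD, n = 3). Neither gene mean passed over all genes (limma adjusted p = 0.0682 and 0.0673). None of 24 haemocyte markers passed (median −0.02), adjusted over the list alone included. A *NimC1* probe had 0.39, while the other spots of its clone had 0.12 and −0.19. *Fer3* had −0.16, and *Hml*, the hemolectin gene of blood cells, had 0.00 with a sign that turned with the scaling. The melanin, catecholamine and clotting list had 0 of 19 (median −0.05), with *yellow-f2* at −0.24. The oxidative stress and detoxification list had *Cyp6g1*, a cytochrome P450 gene, low at −0.47 ± 0.04 (SD, n = 3; limma adjusted p = 0.0441) among 25 genes, and the median was −0.06. *Cyp6g1* was also the member that passed adjusted over the list alone. Heat shock proteins and chaperones had 0 of 11 (median −0.08).

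The midgut, yolk and fat body list had *Fbp2*, a fat body protein gene, low at −0.48 and *Yp2*, a yolk protein gene, low at −0.40, among 23 genes (median −0.02). Adjusted over the list alone, *Fbp2*, *Yp2* and *Jon99Ci* (−0.29) were low, and *Amy-d* (0.46), *Yp3* (0.26) and *Lsp2* (0.25) were high. Among 19 muscle markers, 1 probe of *Msp300*, which encodes a nesprin, was low at −0.40, while the mean of its 5 other probes was 0.06 (list median 0.01). Neuron and glia markers had 0 of 18 (median 0.00), and *jeb* (−0.57) and *Rdl* (−0.33) were low adjusted over the list alone. Tracheal and salivary gland markers had 0 of 11 (median −0.03), with *fkh* at −0.66 ± 0.50 (SD, n = 3) and *PH4alphaSG2* at 0.15. Cytosolic ribosomal protein genes had 0 of 35 (median −0.03), with *RpS19b* at 0.31 and *RpL23* at 0.29.

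Cuticle and chitin genes differed between the arrays. The median of the 34 measured genes was 0.14 on array A, −0.10 on array B and 0.19 on array C, and 0.09 for the gene means. *Cpr56F*, a cuticle protein gene, had 0.95, −0.63 and 1.30 on arrays A, B and C. All 6 measured Tweedle genes of the list (*TwdlT*, *TwdlM*, *TwdlD*, *TwdlG*, *TwdlF* and *Twdlbeta*), which encode cuticle proteins, were positive on arrays A and C and negative on array B, under each scaling as well. *Cpr76Bd* went the other way, with −0.37, 0.88 and 0.17 on arrays A, B and C. *Cpr56F*, *Cpr76Bd* and the Tweedle genes were chosen after their values were seen. No single probe of the list passed over all probes. *Ccp84Aa* was at 0.46 ± 0.13 (SD, n = 3; limma adjusted p = 0.0516), and its gene mean passed over all genes (limma adjusted p = 0.0459) and adjusted over the list alone. *Cpr64Aa* had −0.44.

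**Figure D3:**
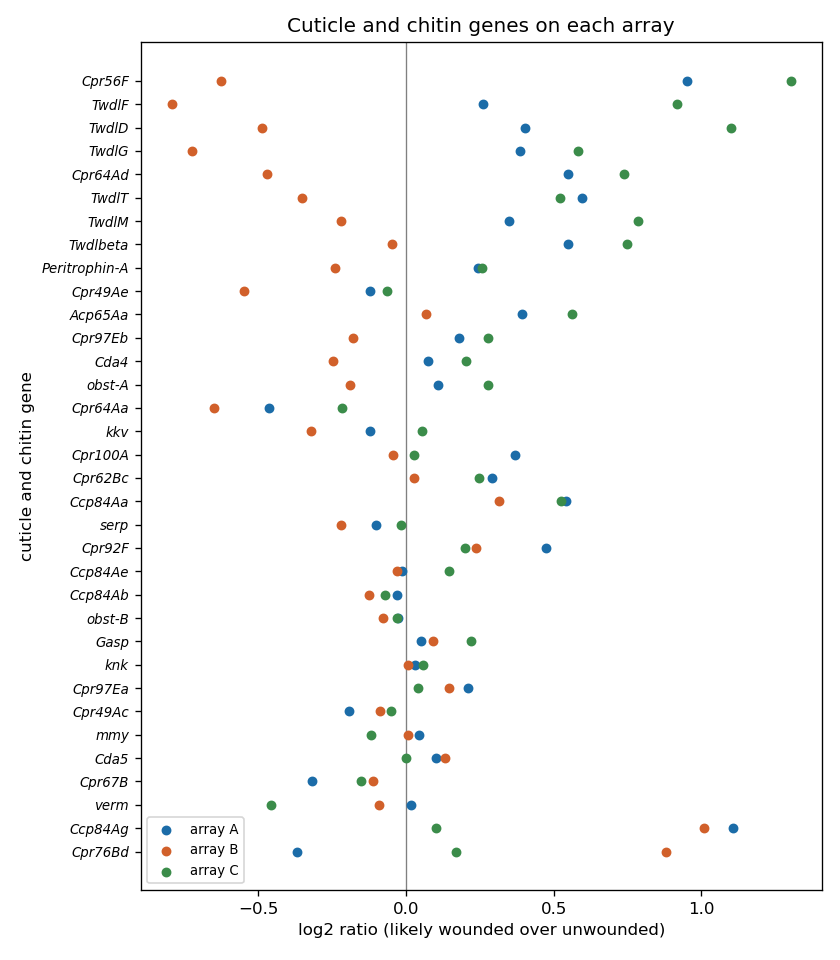
Log2 ratio (likely wounded over unwounded, x axis) of each measured cuticle and chitin gene (y axis) on arrays A, B and C (points). Array B is the lowest of the 3 in 24 of 34 genes, and the Tweedle genes lie above 0 on arrays A and C and below 0 on array B.

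None of the 17 lists passed as a list in camera. With an array left out, the medians of 8 lists changed sign at least once, and that of the heat shock list ran from −0.14 to −0.0038. The smallest p was that of oxidative stress and detoxification, toward low ratios (limma camera adjusted p = 0.259), followed by Toll and Imd, toward high ratios (limma camera adjusted p = 0.330). These 2 lists had an unadjusted p under 0.05. The cuticle list had a limma camera adjusted p of 0.399. The smallest adjusted p was 0.992 with an estimated correlation and 0.778 with fry, whose test of change in either direction passed for 9 lists. That test compares a list with no other genes, and 2184 of all 11887 probes had an unadjusted p under 0.05 in limma. It therefore does not set these 9 lists apart from other genes. Of the 296 listed genes measured, 7 had a probe past the threshold, 1 high and 6 low. Without array B the cuticle list passed toward high ratios (median 0.17, camera adjusted p = 2.25e-04), and without array A the oxidative stress list passed toward low ratios (median −0.09, camera adjusted p = 0.0159). With an estimated correlation neither passed (camera adjusted p = 0.938 without array B and 0.936 without array A).

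**Figure D4:**
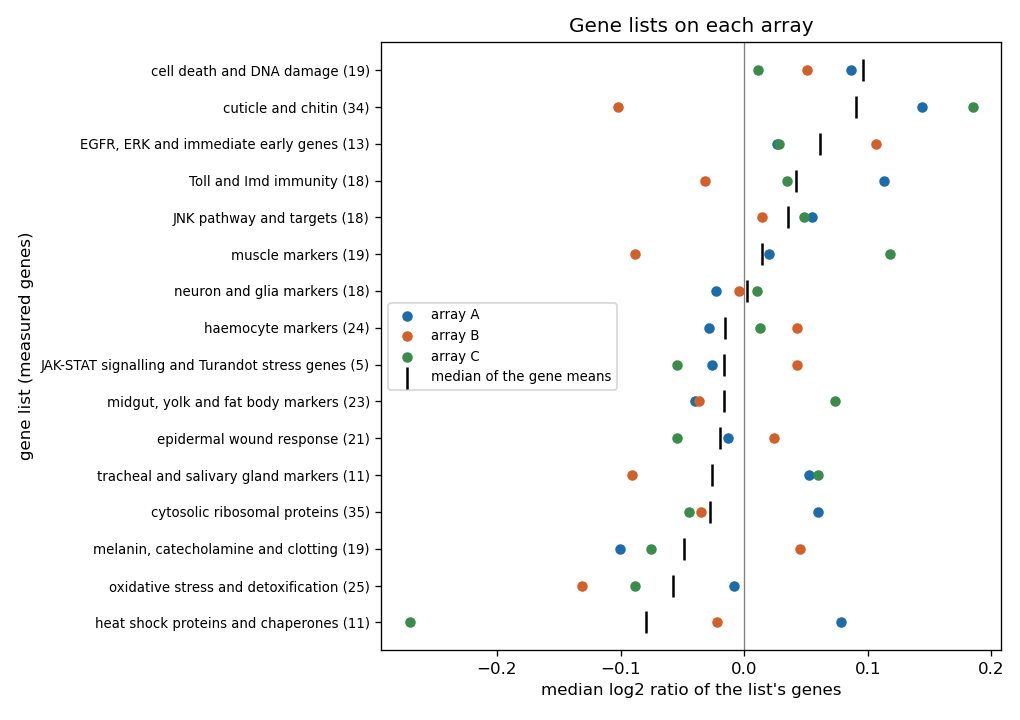
Median log2 ratio (x axis) of each gene list reported (y axis, measured genes in brackets) on arrays A, B and C (points) and for the gene means (bar). The cuticle and chitin list lies at 0.14 and 0.19 on arrays A and C and at −0.10 on array B.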

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

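The tests of clone collections and of plant spots were chosen only after the result was seen. The control spots, left out of the reported comparisons and kept in 1 alternative, carried a signal of their own. Spots named for plant genes had a median log2 ratio of −0.23 (95% bootstrap interval −0.29 to −0.14), and 100 of the 119 with a value on all arrays lay below 0. The fly genomic spots had a median of −0.19, with −0.45 on array B.

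Calls were also spread unevenly over the cDNA libraries the probes came from. Clones of the GH library were 18.2% of tested probes and 51.2% of low calls (one-sided Fisher's exact p = 7.95e-17, taking probes as independent), and clones of the RH library were 8.95% of tested probes and 36.1% of high calls (Fisher's exact p = 5.21e-09). A constant offset of each library is argued against as the whole cause. The median log2 ratio of tested probes was −0.030 for GH and 0.076 for RH. These are small beside the least low call (−0.37) and the least high call (0.37). Centring by values of this size could change the share of GH clones only a little. With each library centred on each array, GH clones still made up 44.9% of the low-ratio probes among the 184 of smallest p (Fisher's exact p = 3.09e-12). In limma 0 probes then passed the threshold, with 2202 at an unadjusted p under 0.05. The median size of the 184 calls went from 0.52 to 0.50 and their median SD from 0.092 to 0.095. The smallest adjusted p went from 0.0441 to 0.0591, on the other side of a threshold that all calls lay close to. A colour imbalance at spots with little fly target may contribute, since the plant spots' median of −0.23 lies toward low ratios and 41 of these spots lie beyond the least low call (−0.37). That median lies nearer to 0 than the least low call, and without spot intensities it stays open, as does a difference in the transcripts that these libraries hold, which was not tested.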

How the results depend on the processing

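The changes of control spots, floor values, linear scale, probes with 1 symbol and clone collections, and the estimated correlation with an array left out, were chosen after seeing the data. Against 61 high and 123 low calls, centring gave 52 and 112, scaling 62 and 144, quantile normalization 70 and 154, values on 2 arrays 51 and 108, robust moderation 69 and 144, and floor values as missing 66 and 134. Array weights, lowest for array B (0.616), gave 184 and 257. Gene means gave 33 high and 112 low genes, and keeping control spots 40 high and 89 low probes. Testing probes with 1 symbol gave 26 and 65. An adjusted p of 0.10 gave 300 and 383. Of the calls, 1 high and 0 low reached 1 in size, and limma's treat at 0.3 gave 0 and 0. The linear ratio gave 0 and 0 (2168 probes at an unadjusted p under 0.05, smallest adjusted p 0.0619) and centred clone collections 0 and 0 (2202, 0.0591). Leaving out 1 array gave 0 to 0 high and 0 to 0 low calls. All 184 kept their sign, which was fixed in advance because each had the same sign on 3 arrays. Their unadjusted p in limma stayed under 0.05, but they had been picked for a small p on these same arrays. At an adjusted p of 0.10, 0, 526 and 428 probes passed without arrays A, B and C. Fewer arrays lower the power there, but the loss was uneven. Without array B, 2365 probes had an unadjusted p under 0.05 in limma, against 2184 with all arrays. Without array A the smallest adjusted p was 0.235. The cause was tested neither here nor for the other changes.

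Lists past the threshold numbered 0 with an estimated correlation, fry, ranks, centring, quantile normalization, values on 2 arrays, floor values as missing and centred collections, and 0 to 1 with an array left out (0 with an estimated correlation as well). The direction check's median ran from −0.060 to 0.0055 with an array left out. *Hsp70Ab* (AT29796), at −0.11, turned to 0.14 with array weights and 0.056 on the linear scale, and ran from −0.62 to 0.15 with an array left out. *Hml* (LP05709), at 0.00, turned to −0.0048 with centring, −0.0034 with scaling, −0.0024 with quantile normalization, −0.058 with array weights and −0.015 with centred collections, and ran from −0.11 to 0.14 with an array left out. The cause was not tested. The other probes named by the fixed rule kept their sign in each setting listed for calls. Of genes named later, *Caf1-55* ran from −0.047 to 0.024 and the re-amplified *Dscam2* spot from −0.082 to 0.19 with an array left out. The filter on dim probes was not run, since no intensities were used, and signal over background limits what can be said of dim probes.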

Other observations

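All tests here were chosen only after the result was seen, except the sign patterns of the arrays. Beside *Pcl* (0.95), *Su(z)12*, a core gene of the Polycomb repressive complex that methylates histone H3, had a high ratio (0.58 ± 0.12, SD, n = 3; limma adjusted p = 0.0441). The other core genes *E(z)* (0.08), *esc* (−0.08) and *Caf1-55* (−0.02) did not pass the test. *Listericin*, an antibacterial peptide gene, had a high ratio (0.44 ± 0.08, SD, n = 3; limma adjusted p = 0.0466). The C-type lectin gene *lectin-24Db* had a low ratio on 1 probe (−0.65) and −0.09 on another. These genes were chosen after their values were seen.

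Turning the sign of array A, B or C gave at most 0 calls, against 184 for the arrays as deposited. Only 1 of the 4 sign patterns gave as many, and 4 patterns are too few for a share under 0.05.

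Other clones of the same gene did not repeat the calls as a set, and 14 of 25 shared the sign. The median of the other clones in the direction of the call was 0.0077 (95% bootstrap interval −0.060 to 0.10). This is the value that drew attention to the pattern, and the called probes were picked for their size, so it cannot test whether the signal belongs to the single probe. Across all 2540 probes with another clone, 63.6% shared the sign (r = 0.22, rho = 0.33, across probes that are not independent). A signal of the single probe and transcript forms that differ between clones both stay open.

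Cuticle genes lay lower on array B than on arrays A and C by a median of −0.24, and B was the lowest in 70.6% of them, against 33.1% of all genes. An offset of array B as a whole is argued against by its median log2 ratio over all values, 0.014. That of array A was 0.0014 and that of array C −0.0043. Of 10000 random lists of that size, 0 lay as low (percentile 0). The cuticle list was picked for this value, so its rank is no separate test. A candidate explanation is a difference in age between the wounded and unwounded pools of an array. Muscle markers, also late genes, lay at −0.20 (percentile 0.01). Which arrays would be concerned cannot be told, since the Tweedle medians were 0.39 on array A, −0.42 on array B and 0.77 on array C. Random lists ignore correlation within a list, estimated at 0.30 for cuticle and 0.51 for muscle, so these percentiles overstate how rare the values are. Fly genomic spots also lay low on array B, at a median of −0.45, against −0.07 on arrays A and C. An effect of array B on some spots therefore stays open too. Of lists not chosen for late genes, melanin (percentile 98.47) lay outside the middle 95% of random lists, on the high side, and Toll and Imd (2.54) and oxidative stress (4.92) lay inside it. Tracheal and salivary gland markers, of which 4 of 11 are shared with the cuticle list, lay at percentile 16.04. Neuron and glia markers lay at 24.87, midgut, yolk and fat body markers at 7.75 and haemocyte markers at 86.84. Embryo age thus stays open, and the labels give no ages.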
